A study of Mus musculus with 2 samples.

How the data were processed

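Histone H3 acetylated at lysine 27 (H3K27ac), a mark found at active promoters and enhancers, was measured by ChIP-seq in the facial prominence of mouse embryos at day 11.5. The labels give 2 biological replicates of 1 group. Replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos of mixed sex, and per the labels' protocols chromatin was sheared to fragments of 300 to 500 bp. There was no treatment, other stage or other tissue to compare with, so the analysis compared the replicates with each other, and genes and chromosomes with one another within the peak lists.

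The authors deposited 4 peak lists in narrowPeak format on the mm10 build, per the file descriptions that accompany them. Peaks were called for replicate 1 alone, for replicate 2 alone and for both replicates pooled. A further list, called the replicated list here, was derived from the pooled list and the lists of both replicates. Per those descriptions the lists of replicate 1 and of the pool were made with 2 control files and the list of replicate 2 with 1 of those 2. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. Every value per peak is the authors'. The deposited signal value is a linear fold enrichment of the ChIP over its control, a ratio with no replicate error. The deposited significance columns are −log10 of a p-value and −log10 of a q-value. The last column is the distance of the summit from the start of the peak. Fold enrichments were used to describe, rank, filter or compare peaks within 1 list, and across lists only in a rank correlation at peaks that both replicates' lists held. The lists hold no read counts, so the sequencing depth of each replicate is unknown and no interval that depends on depth is given.

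The lowest −log10 p among the deposited peaks was 2.02 in replicate 1, and 2.05 in each of the other 3 lists. A q of 0.05 or less was reached by 60.1% of peaks in replicate 1, 76.9% in replicate 2, 75.4% in the pooled list and 95.1% in the replicated list. All 25741 replicated peaks were rows of the pooled list. Of them, 18010 (70.0%) overlapped a peak in the list of each replicate by at least 1 bp, 5815 overlapped a peak of replicate 1 only, 1382 of replicate 2 only and 534 of neither. The authors' rule for the replicated list is not given in the sources used here. All 17812 pooled peaks that overlapped a peak of each replicate by at least 50% of one or the other peak were in it, and they made up 69.2% of it. "Replicated" is therefore the name of the list, not a statement that both replicates' lists hold every peak.

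Genes were taken from the GENCODE vM21 annotation of the matching assembly (21853 protein-coding genes with 54361 transcription start sites, TSS), and sequence from the reference genome of that assembly. No peak ran past a chromosome end. A gene was called marked where a peak overlapped the 1 kb on either side of a TSS by at least 1 bp, and peaks outside all such windows were called distal. Overlaps and shuffles within chromosomes outside assembly gaps used bedtools 2.31.1, and other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

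The tests, 20 gene lists (382 entries, all matched, 375 distinct genes), the rule for naming genes and most alternatives were fixed before the data were examined. Overlap of peak lists was set against 100 shuffles. Promoter marking of each list was compared with all other protein-coding genes by a 2-sided Fisher's exact test, and the median number of distal replicated peaks within 100 kb of a TSS with 100000 random lists of the same size by a 2-sided permutation test, each with Benjamini-Hochberg adjustment over the 20 lists. An exact adjusted p is that of Fisher's exact test. Genes are not independent replicates, and neighbouring genes share peaks, so these tests describe these lists of peaks. Replicated peaks no more than 10 kb apart were stitched into domains ranked by the bases that peaks cover. For 9 short consensus sequences, windows of 250 bp either side of distal summits were compared with windows of the same length 5 kb away that lay outside every peak and promoter, by a 2-sided Fisher's exact test with Benjamini-Hochberg adjustment. Odds ratios are given with 0.5 added to each count. Shares carry 95% Wilson intervals, or exact binomial intervals for chromosomes, that treat peaks or genes as independent.

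Genes are named by rule. They are up to 4 members of each list with the highest fold enrichment at the promoter, the unmarked members where a list had at most 6, the genes at the 20 stitched domains with the most bases in peaks, and the 10 genes with the widest promoter peaks or the most distal peaks. All other genes named were chosen after their values were seen.

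The functions were tested on simulated peaks first. With 60.2% of 31158 peaks planted as shared, 60.4% were recovered. All 200 planted marked genes among 21853 were recovered, with 24 further genes that have a TSS within 1 kb of a planted peak. Of 200 random lists of 20 genes, 9 had an unadjusted Fisher p under 0.05 and none passed after adjustment. For distal peaks 2 of the 200 random lists had an unadjusted permutation p under 0.05. A list with planted distal peaks was called, and 50 of 50 planted domains were stitched.

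Alternatives were other overlap rules, other windows, stricter peak thresholds, the pooled list, each replicate's list alone, a background matched on promoter CpG content, random lists matched on gene density, other stitching and ranking of domains, and shuffled consensus letters. Signal tracks and alignments were not used here.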

Results

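H3K27ac was profiled in the facial prominence of mouse embryos at day 11.5, the tissue of neural crest mesenchyme, surface epithelium, vessels and nerves from which the jaws and face form. The 2 biological replicates were pools of 109 embryos (replicate 1) and 88 embryos (replicate 2). The authors called 67217 peaks in replicate 1, covering 25.2 Mb, and 31161 in replicate 2, covering 13.9 Mb. The pooled list held 46506 peaks and the replicated list 25741 peaks over 17.6 Mb. Median peak width was 244 bp in replicate 1, 294 bp in replicate 2 and 486 bp in the replicated list. Depth is unknown because the lists hold no read counts. Fold enrichments are the authors' values for single peaks and carry no error.

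The first question was how far the replicates' lists held the same regions. The strongest peaks were shared. Among peaks in the highest decile of fold enrichment, 97.8% of replicate 1 peaks and 99.9% of replicate 2 peaks overlapped a peak in the other list, against 9.06% and 45.4% in the lowest decile. Over whole lists, 30.2% of replicate 1 peaks (95% Wilson interval 29.8 to 30.5) overlapped a replicate 2 peak, and 67.6% of replicate 2 peaks (67.0 to 68.1) overlapped a replicate 1 peak. The highest of 100 shuffles gave 1.20% and 2.36%. With the 31161 top peaks taken from both lists, the shares were 52.8% and 57.7%. Across the 21050 shared replicate 2 peaks, the fold enrichments in the 2 lists had a Spearman rho of 0.601 (95% bootstrap interval 0.591 to 0.611). This is a correlation across peaks, which are not independent replicates. It was 0.671 for promoter peaks and 0.439 for distal peaks.

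**Figure D1:**
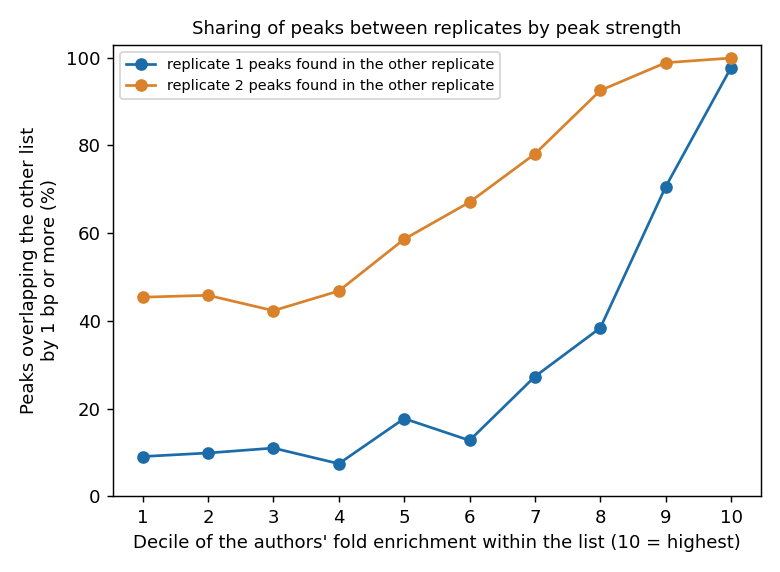
Share of peaks (%) that overlap a peak of the other replicate by at least 1 bp (vertical axis), by decile of the authors' fold enrichment within each list (horizontal axis). Each point is 1 decile of 1 list, and peaks with equal fold enrichment were divided between neighbouring deciles by position. In the highest decile 97.8% of replicate 1 and 99.9% of replicate 2 peaks were shared, against 9.06% and 45.4% in the lowest.

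Promoter peaks were shared more often than distal peaks. In replicate 1, 62.6% of 16607 promoter peaks and 19.5% of 50610 distal peaks were found in replicate 2, a difference of 43.0 percentage points (95% interval 42.2 to 43.9). In replicate 2 the shares were 85.8% of 12365 and 55.5% of 18796, a difference of 30.3 points (29.4 to 31.2). Promoter peaks were also wider and stronger. In the replicated list their median width was 601 bp and median fold enrichment 6.12, against 418 bp and 4.18 for distal peaks. Within deciles of fold enrichment the difference in sharing was 14.9 points in replicate 1 and 11.9 points in replicate 2, and within deciles of width 20.2 and 12.4 points. These are means over deciles weighted by their promoter peaks. In the lowest fold decile the differences were 15.6 and 25.2 points. In the highest nearly all peaks were shared (98.7% of promoter and 95.4% of distal peaks in replicate 1), which left little room for a difference.

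The next question was where in the genome the replicated peaks lay. Of the 25741 peaks, 11359 (44.1%, Wilson interval 43.5 to 44.7) overlapped a promoter window of a protein-coding gene, against at most 3.77% in 100 shuffles. A further 2.97% lay at the TSS of a noncoding RNA gene. The summits of the remaining peaks fell in introns for 29.2% of all peaks, in exons for 4.11% and between genes for 19.6%. In 20 shuffles the means were 41.3%, 4.14% and 50.1%, again of all peaks. Only 3.59% of shuffled peaks lay at protein-coding promoters, so the lower intron share does not show that peaks avoid introns. Away from promoters, more replicated peaks lay in introns (7508) than between genes (5052), the reverse of the shuffles. The share at promoters depended on the list. It was 32.2% in the pooled list, 39.7% in replicate 2 and 24.7% in replicate 1, and 61.0% in the stronger 50% of replicated peaks.

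The replicated list marked the promoters of 9285 of 21853 protein-coding genes (42.5%). Replicate 1 alone marked 10797 genes (49.4%) and replicate 2 alone 9128 (41.8%). Marking followed the CpG content of the promoter. In the lowest decile of genes by CpG observed over expected 0.595% were marked, and in the highest decile 87.8%.

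Transcription factors of the neural crest and facial mesenchyme were marked more often than other genes. Of the 40 genes, 36 (90.0%) had a promoter peak, against 42.4% of the other genes (Fisher's exact test, adjusted p = 1.35e-08), and 36 were also marked in each replicate's own list. The highest promoter peaks belonged to Alx4, an aristaless-type homeobox gene of the frontonasal mesenchyme, and Prrx1, a paired-related homeobox gene of the limb and facial mesenchyme. The Alx4 peak (chromosome 2, 93641731 to 93646831, mm10) had a fold enrichment of 37.9 in the replicated list, 34.4 in replicate 1 and 30.1 in replicate 2. The Prrx1 peak (chromosome 1, 163307511 to 163315665) had 32.7, with 30.2 and 25.4 in the replicates. Eya1, a transcriptional coactivator, and Foxp1, a forkhead gene, each reached 27.1. The 4 unmarked members, Osr1, Osr2, Tbx22 and Lmx1b, had no promoter peak in either replicate's list. The call held against genes of the same CpG deciles, of which 65.0% were expected to be marked (95% range of random lists 50 to 77.5, permutation test, adjusted p = 0.0012).

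Genes that pattern the jaw were marked in 22 of 26 cases (84.6%, Fisher's exact test, adjusted p = 8.54e-05), and in 23 in each replicate's list. Nr2f1 (chromosome 13, 78197137 to 78199980), a COUP-TF nuclear receptor, had a fold enrichment of 49.0, with 40.8 in replicate 1 and 38.5 in replicate 2. Nr2f2 had 25.3, Dlx6, a distal-less homeobox gene of the lower jaw, 18.1. The T-box gene Tbx2 had a promoter peak of 8932 bp. The unmarked members were Dlx3, Hand1, Edn1 and Nkx3-2. Nkx3-2 had weak peaks in both replicates' lists, of fold enrichment 2.72 and 3.84, yet none in the replicated list. It was 1 of 207 genes marked in both replicates' lists but not in the replicated list. Edn1, the endothelin ligand that specifies the lower jaw, and Hand1 had none in any of these 3 lists. Against genes of the same CpG deciles (65.4% expected) the call was lost (permutation test, adjusted p = 0.102), as it was where a peak had to cover the TSS base itself (Fisher's exact test, adjusted p = 0.0804).

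Among 41 facial signalling genes 28 were marked (68.3%, Fisher's exact test, adjusted p = 0.00359). The hedgehog receptor gene Ptch1 had a fold enrichment of 40.7 (chromosome 13, 63562645 to 63567170), the Wnt feedback gene Axin2 37.4, the TGF-beta and BMP inhibitor Smad7 36.3 and the hedgehog effector Gli3 30.7. In replicate 1 these values were 34.9, 30.2, 31.1 and 23.6, and in replicate 2 30.9, 28.8, 29.2 and 20.6. The ligand genes of this list are named after their values were seen and were not tested as a group. Of them Wnt5a had a fold enrichment of 18.3, Tgfb3 11.9, Tgfb2 7.76 and Bmp7 6.995, while Bmp2, Bmp4, Fgf8, Fgf10, Shh, Wnt3, Wnt9b and Wnt11 were among the 13 unmarked members. Fgf10 had promoter peaks in both replicates' own lists (4.79 and 3.71), and Bmp4 and Wnt11 in that of replicate 2. This call too was lost against genes of the same CpG deciles (65.9% expected, permutation test, adjusted p = 0.968). Housekeeping genes were marked in 17 of 20 cases (Fisher's exact test, adjusted p = 0.000663, and 0.32 by permutation test with CpG matching). Actb had a fold enrichment of 45.3, Ywhaz 27.1, Tuba1a 24.1 and Polr2a 19.8. The unmarked members were Tbp, B2m and Sdha, each with a weak peak in at least 1 replicate's list.

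In the replicated list, genes of the other cell types of the face did not pass the test in either direction, except those of blood. Oral and surface epithelium had 10 of 22 genes marked (45.5%, exact adjusted p = 0.875), with Sox2 at a fold enrichment of 12.4 and Pitx2, Esrp1 and Perp between 4.74 and 5.29. The cartilage and bone list had 8 of 15 (53.3%, exact adjusted p = 0.518). Among them Col9a1 had a fold enrichment of 10.3, the osteoblast regulator Runx2 9.43, the cartilage collagen Col2a1 9.21 and Dlx5 8.64. Neurons, ganglia and glia had 8 of 20 (exact adjusted p = 1.0), led by Elavl4 at 6.95, Isl1 at 5.29, Ascl1 at 5.01 and Tubb3 at 4.74. The forebrain and eye list had 8 of 16 (exact adjusted p = 0.685), led by Dlx1 at 14.0 and Dlx2 at 12.8, which are also jaw genes, then Six3 at 9.43 and Emx2 at 7.78. Endothelium had 5 of 18 (exact adjusted p = 0.3), with no member above the 5.84 of Egfl7, while Lyl1 had 3.63, Tal1 3.34 and Emcn 3.12. Muscle precursors had 3 of 14 (exact adjusted p = 0.233). These were Pax7 at 5.86, Tbx1 at 4.18 and Msc at 3.91. In replicate 1's own list 16 of 22 epithelial, 10 of 18 endothelial, 14 of 20 neuronal and 6 of 14 muscle genes were marked, and none of these lists passed (exact adjusted p = 0.0504, 0.715, 0.107 and 0.832). Among the stronger 50% of replicated peaks, epithelium (9.09% marked) and endothelium (5.56%) were below other genes (exact adjusted p = 0.0194 and 0.0191), as was endothelium with overlap in both replicates, a setting chosen after seeing the data (2 of 18, exact adjusted p = 0.0394).

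Genes of blood cells and of organs outside the face were marked less often than other genes. In the erythroid list 1 of 16 was marked (Tal1, also in the endothelial list, exact adjusted p = 0.00666). Some globin genes of this list are near-identical copies, so their lack of peaks is uncertain. No gene was marked among 12 of macrophages (adjusted p = 0.00423), 12 of lymphocytes (0.00423), 15 of intestine and pancreas (0.00122), 14 of germ cells (0.00185) or 10 of photoreceptors (0.0112, all by Fisher's exact test). The liver list had 1 of 16 (Foxa3, at 4.74, exact adjusted p = 0.00666) and the heart list 2 of 16 (Myl4 at 11.3 and Myh7 at 4.7, exact adjusted p = 0.0306). The heart call was lost in each replicate's own list (5 of 16 in replicate 1 and 4 of 16 in replicate 2, exact adjusted p = 0.263 in each), in the pooled list (exact adjusted p = 0.538) and with overlap in both replicates, chosen after seeing the data (exact adjusted p = 0.0566). The intestine and pancreas call was lost in the list of replicate 2 (3 of 15, exact adjusted p = 0.166), and the photoreceptor call where a peak had to cover the TSS base itself (exact adjusted p = 0.063). Many promoters in these lists are poor in CpG. With CpG matching, from 8.33% to 25% of the genes of 6 of these lists were expected to be marked and their calls were lost. These were erythroid cells (permutation test, adjusted p = 0.977), macrophages, liver and photoreceptors (0.968 each), heart (0.41) and lymphocytes (0.389). Except for heart, these calls could not have been kept, because their random lists ranged down to 0% marked, and their loss decides nothing. The call remained for intestine and pancreas (permutation test, adjusted p = 0.0113) and germ cells (0.004).

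Hox genes set position along the body axis. None of the 28 trunk Hox genes was marked in the replicated list or in either replicate's list (exact adjusted p = 2.13e-06). From their CpG content 64.3% were expected to be marked (95% range 46.4 to 78.6, permutation test, adjusted p = 0.0004). These genes lie in 4 clusters and are not independent. Of 11 anterior Hox genes, 2 were marked (18.2%, exact adjusted p = 0.188), 5 in replicate 1's list and 2 in that of replicate 2, and none of these counts differed from other genes past the threshold. Those in the replicated list were Hoxa2, which specifies the second pharyngeal arch, with a fold enrichment of 7.78 (chromosome 6, 52162960 to 52164893), and Hoxb2 with 7.19. The difference between trunk and anterior lists was not tested. Of the 57 distinct marked genes named by the rule for lists, wide peaks and distal counts, 52 had a promoter peak in both replicates' lists. Msc had none in replicate 1, and Emcn, Foxa3, Lyl1 and Tubb3 had none in replicate 2.

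**Figure D2:**
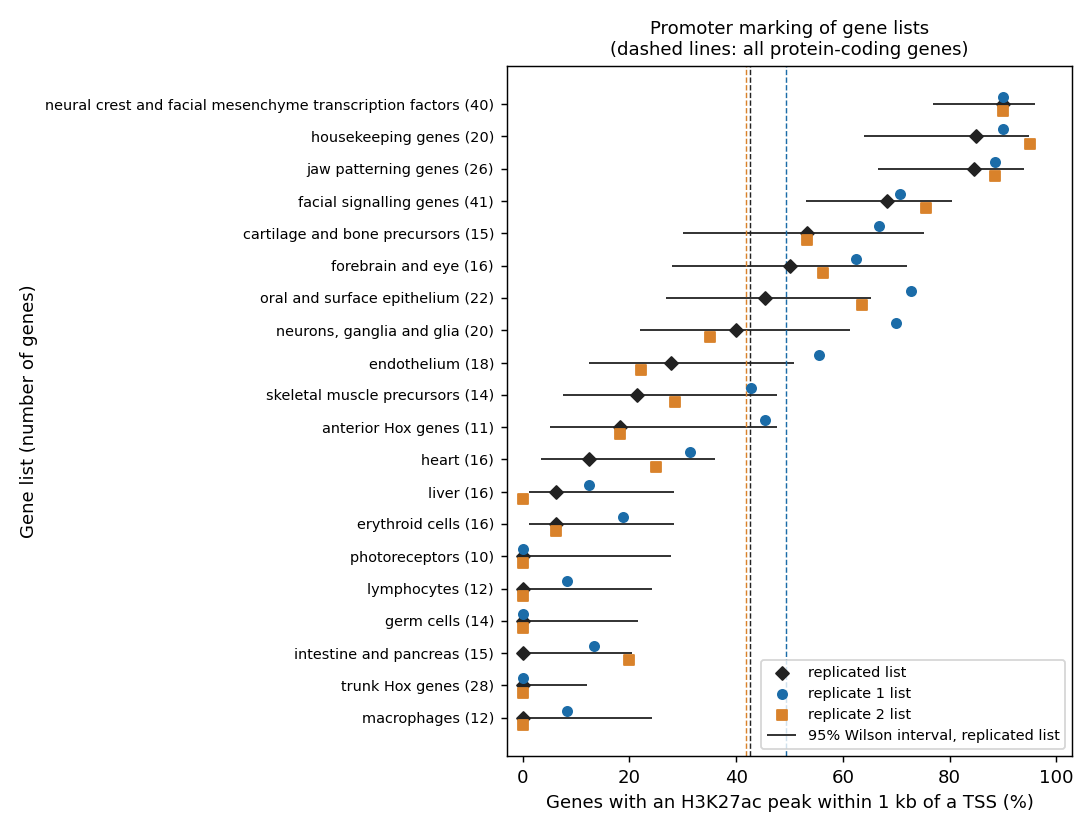
Share of genes (%) with an H3K27ac peak within 1 kb of a TSS (horizontal axis) for the 20 gene lists (vertical axis, number of genes in parentheses). Diamonds are the replicated list with 95% Wilson intervals, circles replicate 1, squares replicate 2, and dashed lines the share among all protein-coding genes in the list of the same colour (42.5%, 49.4% and 41.8%). Neural crest and facial mesenchyme transcription factors were at 90.0% in all 3 lists and trunk Hox genes at 0%.

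Distal peaks were then counted around each gene. The median protein-coding gene had 0 distal replicated peaks within 100 kb of a TSS (mean 1.76). Jaw patterning genes had a median of 9 and random lists of the same size 0.5. Neural crest and facial mesenchyme transcription factors had 6 and facial signalling genes 4, and random lists had 0 for both. Each of these 3 lists had an adjusted p of 0.000133 by permutation test, the smallest that 100000 random lists can give here. They were also past the threshold in each replicate's own list. The random lists were not matched on promoter marking, which was more frequent in these 3 lists than in other genes. Nor were they matched on the number or spread of a gene's TSS, which set the width of the region counted. In replicate 1 the medians were 17.5, 14.5 and 12, against 3.5, 3.5 and 4 in random lists, and in replicate 2 they were 10.5, 6.5 and 5, against 1 for each. Alx4 had 21 such peaks, Foxp1 20, Nr2f1 and Nr2f2 15 each, and Smad7 28. Housekeeping genes had a median of 3.5 (permutation test, adjusted p = 0.0053). That call was lost in replicate 1 (permutation test, adjusted p = 0.0578) and in replicate 2 (0.0912). Cartilage and bone precursors had 3 (permutation test, adjusted p = 0.0777), and were past the threshold in replicate 1 (0.0209) and in replicate 2 (0.0016). The other 15 lists had medians between 0 and 2 and did not pass (permutation test, adjusted p from 0.193 to 1.0). With replicated peaks only higher counts could be detected, because the range of random medians reached down to 0 for every list. Of the 15, anterior Hox genes were past the threshold in replicate 2 (median 6, random lists 1, permutation test, adjusted p = 0.0076). These genes lie in 3 clusters whose members count the same peaks, so they are not independent. With 1 gene per cluster in the replicated list they did not pass either.

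**Figure D3:**
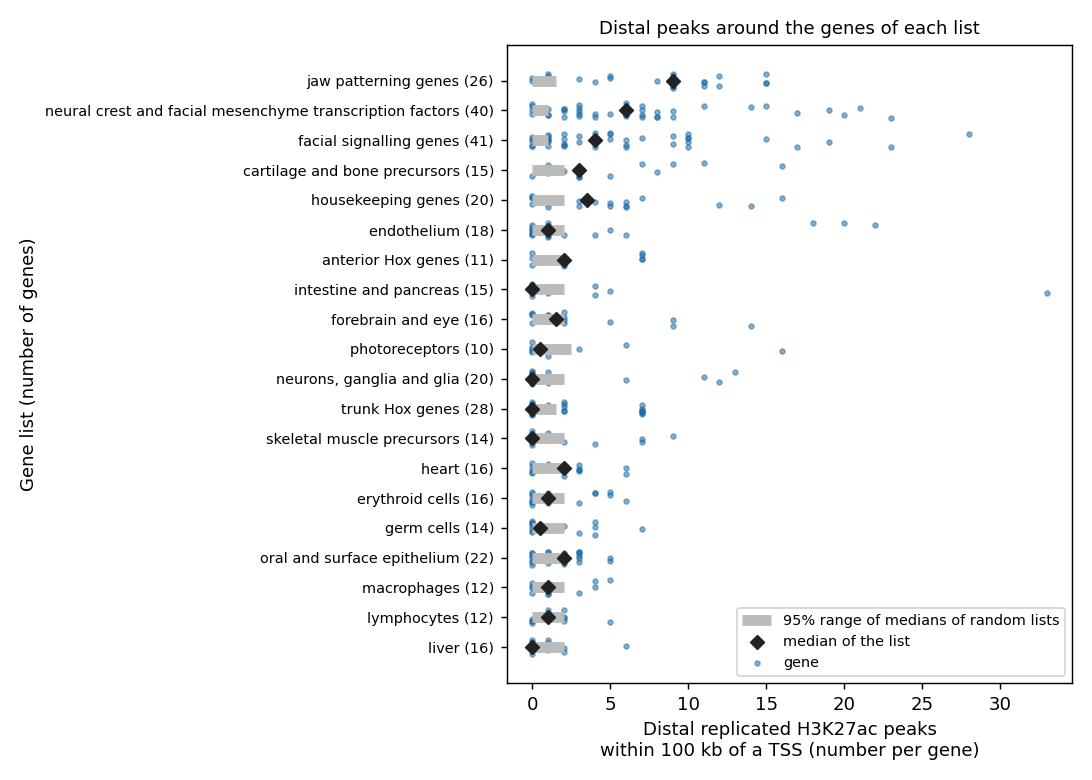
Number of distal replicated peaks within 100 kb of a TSS (horizontal axis) for each gene (dots) of the 20 lists (vertical axis). Diamonds are list medians and grey bars the 95% range of medians of random lists of the same size. Jaw patterning genes had a median of 9, neural crest and facial mesenchyme transcription factors 6 and facial signalling genes 4, all beyond their grey bars.

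The genes with the most distal replicated peaks were Gse1 on chromosome 8 with 60, Mrpl23, Tnnt3 and Lsp1 side by side on chromosome 7 with 42, 42 and 41, Src on chromosome 2 with 37, Cpa5 on chromosome 6 and Sept9 on chromosome 11 with 35 each, and Cpa1, 1700001O22Rik and Igfbp4 with 33 each. Neighbours count the same peaks. A gene whose TSS lie far apart, such as Gse1 (120228456 to 120581390), is counted over a wider region, and these counts were not scaled for that. Cpa1 and Cpa5 are carboxypeptidase genes with no promoter peak in the replicated list.

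The widest promoter peaks lay at Tnrc18 (chromosome 5, 142812743 to 142824560, 11818 bp, fold enrichment 59.7), Setd1b (9206 bp), Tbx2 (8932 bp), Rarg (8824 bp), Meis2 (8166 bp), Prrx1 (8155 bp), Id3 (7285 bp), Nr2f2 (7024 bp), Zfp532 (6887 bp) and Lzts2 (6864 bp). Setd1b encodes a histone methyltransferase, Rarg a retinoic acid receptor and Id3 an inhibitor of basic helix-loop-helix factors. These widths differed between lists. The widest peak at Tnrc18 was 6615 bp in replicate 1 and 8606 bp in replicate 2, and at Setd1b 2531 bp and 2265 bp.

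Stitching gave 14387 domains, of which 8777 were a single peak. The domain with the most bases in peaks lay on chromosome 7 from 142505755 to 142579105, with 37 peaks covering 36752 bp. It holds the TSS of Mrpl23 and of H19, Nctc1 and Prr33, which the annotation used here lists as noncoding. Igf2 lies outside it on the H19 side. The domain at chromosome 6, 50908481 to 51015704, had 35 peaks covering 29372 bp. It lies between protein-coding genes, 254042 bp from the nearest protein-coding TSS, that of Npvf. Histone gene clusters on chromosome 13 gave the third (23529910 to 23593503, 14 histone genes) and the twelfth domain (9 histone genes). Their genes are similar copies, so the peaks assigned to single members are uncertain. The fourth lay within Dnm3 on chromosome 1 (161997076 to 162054464), and the fifth between protein-coding genes on chromosome 2 (30676791 to 30726569), 75138 bp from the TSS of 1700001O22Rik. The fifth holds the TSS of the noncoding RNA genes Gm14486 and Gm14488. The next held Cdc6 and the retinoic acid receptor gene Rara (chromosome 11), Nr2f2 (chromosome 7), Zmynd8, and Mllt10 with Skida1 and A930004D18Rik (chromosome 2), Trio (chromosome 15) and Bahcc1 (chromosome 11).

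Ranked from 13 to 20 were a domain on chromosome 6 with Cpa2, Ssmem1 and Tmem209, Dusp7 on chromosome 9, Prrx2 with Asb6 on chromosome 2, Cep41 with Cpa1 on chromosome 6, Fignl1 on chromosome 11, a region of chromosome 17 that lies 90961 bp from the TSS of Haao, a region within Gse1 on chromosome 8 and Tbx2 on chromosome 11. Of the 20 domains, 17 overlapped the 20 domains with the most bases in peaks of replicate 2 alone and 15 those of replicate 1 alone. With ranking by fold enrichment times width 7 of the 20 remained, and with 5 kb stitching 12.

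**Figure D4:**
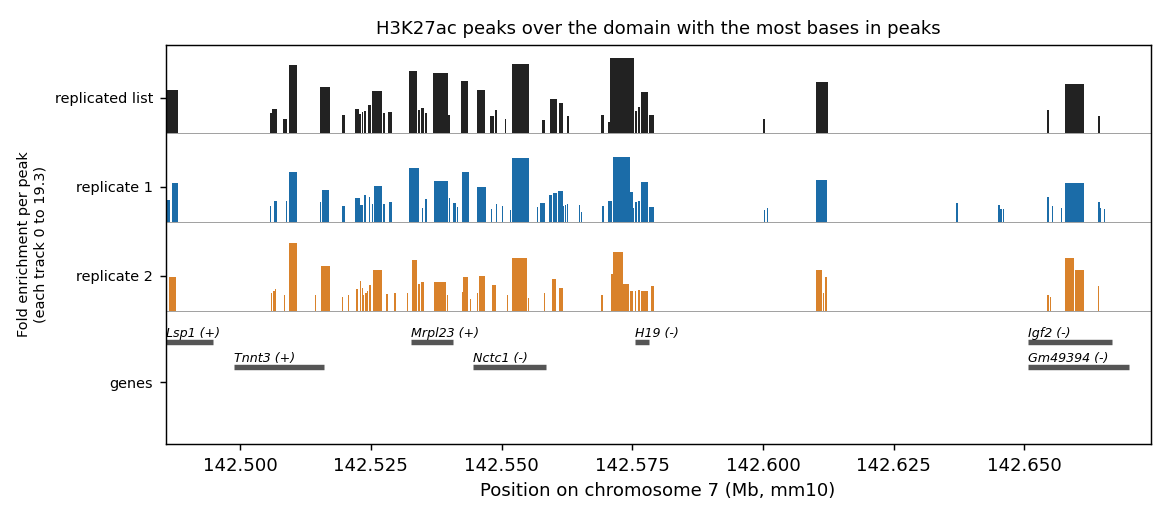
H3K27ac peaks over the stitched domain with the most bases in peaks and the neighbouring Igf2 gene on chromosome 7 (position in Mb, mm10). Bars show each peak's position, width and the authors' fold enrichment (vertical axis, the same scale in each track) in the replicated list and the 2 replicates, and grey bars show protein-coding genes and the noncoding genes H19 and Nctc1 with their strand. The 37 replicated peaks of the domain run from within Tnnt3 to just past H19.

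Chromosomes were compared last. The X chromosome held 2.8 replicated peaks per Mb outside assembly gaps, and the autosomes between 7.33 (chromosome 14) and 18.4 (chromosome 11). The X was below every autosome in each replicate's list as well, with 5.77 peaks per Mb in replicate 1 (lowest autosome 20.3) and 2.99 in replicate 2 (lowest autosome 8.89). For distal peaks the X had 1.06 per Mb and the autosomal median was 5.81. Of 948 X-linked protein-coding genes, 232 were marked (24.5%, exact binomial interval 21.8 to 27.3), against 34.5% (32.4 to 36.6) on chromosome 7, the lowest autosome, and 50.9% (47.0 to 54.9) on chromosome 12, the highest. The Y chromosome had 1 peak.

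**Figure D5:**
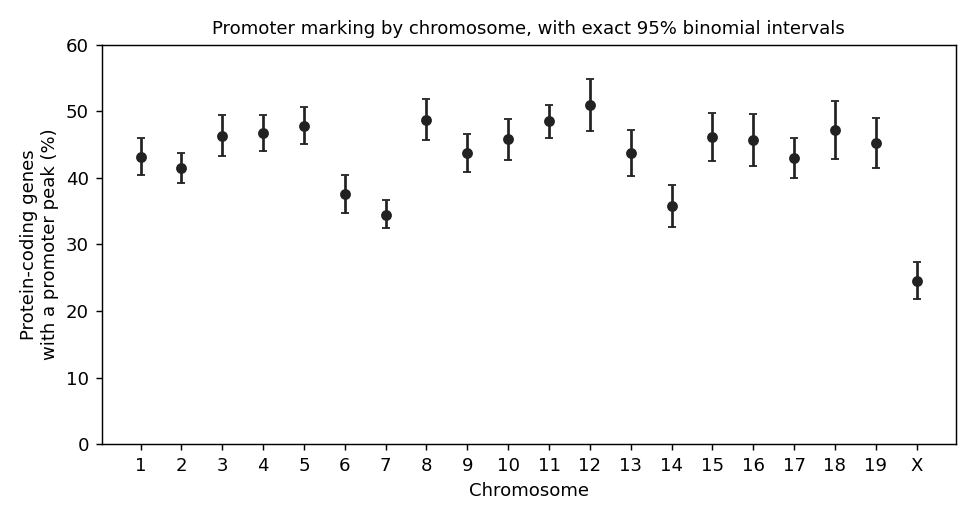
Share of protein-coding genes (%) with a replicated promoter peak (vertical axis) on each autosome and the X chromosome (horizontal axis). Points are the shares and bars exact 95% binomial intervals, and the X chromosome, at 24.5%, lies below every autosome.

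Short consensus sequences were counted in distal peaks and in windows 5 kb away. Distal windows were richer in G and C (51.1% against 45.7%), so each consensus was also set against 20 versions with shuffled letters (13 for the homeodomain consensus, which has few distinct versions). The TEAD consensus GGAATG was in 28.1% of distal windows, with an odds ratio of 1.20 over the flanks (95% interval 1.15 to 1.26, Fisher's exact test, adjusted p = 3.45e-14), above all 20 shuffled versions (highest 1.17). In distal peaks found in only 1 replicate's list it was not above all of them (1.13 with a highest of 1.16 in replicate 1, and 1.17 with 1.19 in replicate 2). The homeodomain consensus TAATTA was less frequent than in flanks (odds ratio 0.713, 0.665 to 0.765, exact adjusted p = 1.74e-21), yet above all 13 shuffled versions (highest 0.645). The TFAP2 consensus GCCNNNGGC had an odds ratio of 2.14 (exact adjusted p = 1.54e-142), and 17 of its 20 shuffled versions had as large a value. Shuffling a consensus with both C and G can spell CG where the consensus does not. The comparison therefore cannot decide on TFAP2. The bHLH consensus CATCTG had 1.13 (exact adjusted p = 7.42e-08) and the SOX consensus ACAATG 0.826 (exact adjusted p = 1.23e-13), both within the range of their shuffled versions.

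Of the control consensuses, GATA (AGATAA) had an odds ratio of 0.684 (exact adjusted p = 7.46e-47) and HNF4 (CAAAGTCCA) 1.39 (exact adjusted p = 0.0115), within the range of their shuffled versions. MEF2 (CTAAAAATA) had 1.03 (exact adjusted p = 0.931), above all 20 of its shuffled versions (highest 0.829). Over whole peaks MEF2 had 0.969 and was no longer above all of them (highest 1.05). The CTCF consensus CCACNAGGTGGCAG was in 4 distal windows and 6 flanks, too few to compare.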

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

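Alternatives that ask for a q of 0.05 or less, for overlap in both replicates' lists, for 1 list member per cluster, or for promoter width in either replicate's list were chosen after seeing the data. The overlap of replicate 1 with replicate 2 (30.2%) was 21.7% with 50% of the peak covered, 18.6% with 50% reciprocal overlap, 37.7% in the stronger 50% of each list, 52.8% with equal numbers of top peaks and 40.4% at a q of 0.05 or less. That of replicate 2 with replicate 1 (67.6%) was 57.3%, 40.1%, 82.8%, 57.7% and 71.3%. The correlation at shared peaks (0.601) was 0.631 for the p column and 0.756 with reciprocal overlap. The excess of promoter over distal sharing kept its direction under all 4 overlap and strength settings. In replicate 1 (43.0 points) it was 37.0, 33.0, 40.2 and 39.3 points, and in replicate 2 (30.3 points) it was 31.7 with 50% of the peak covered, 18.5 in the stronger 50% and 34.3 with equal numbers. The share of peaks at promoters (44.1%) was 48.7% with 2.5 kb windows, 26.1% at the TSS base, 32.2% in the pooled list, 61.0% in the stronger 50%, 45.4% at a q of 0.05 or less, 52.0% with overlap in both replicates, and from 24.7% to 39.7% with either replicate left out. The domains with the most bases in peaks kept 12 of 20 with 5 kb stitching and 7 of 20 with ranking by fold enrichment times width. The X over the autosomal median (0.284) was 0.401 per protein-coding gene and from 0.217 to 0.239 with either replicate left out. Relative to the median of shuffled letters, 2 of the consensuses past the threshold changed direction, homeodomain to 1.26 and TFAP2 to 0.753. CTCF, in too few windows to compare, went to 0.693. TFAP2, bHLH (1.14), SOX (0.992), HNF4 (1.31) and GATA (0.972) fell within the range of their shuffled versions. HNF4 over whole peaks had an odds ratio of 1.25, no longer past the threshold. Shuffling keeps base composition, which differs between peaks and flanks, but not pairs of neighbouring letters. Shuffled versions of TFAP2, bHLH, SOX and HNF4 can spell CG where the consensus does not, so the change of direction of TFAP2 decides nothing. The causes of the other changes were not tested.

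With CpG matching the lists called higher fell from 4 to 1 and those called lower from 9 to 3. Except for heart, the lower calls that were lost could not have been kept, because their random lists ranged down to 0% marked. Under the 8 other settings the number of lists called higher was 3 or 4 and of lists called lower 7 to 11. For distal peaks the number called higher was 3 to 5 under the 8 alternatives, and 0 lists were called lower under any. With replicated peaks within 100 kb the range of random medians reached down to 0 for every list. No list could therefore have been called lower in that setting, and the lack of lower calls there decides nothing. Over single lists and named promoter peaks, 421 values kept their direction and their side of the threshold, or in the case of promoter peaks were present in the list of the replicate kept, 20 list calls were lost, 8 were gained and 0 reversed. No paired analysis was possible because there is 1 group. What depth limits cannot be assessed from lists that hold no read counts.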

Other observations

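The tests of list length at a q of 0.05, of the X chromosome, of promoter peak width in single replicates and of 1 imprinted gene per cluster away from the loci seen first were chosen only after those results were seen, and the imprinted list was written after the domains were seen. The tests of scatter, of the homeodomain consensus, of all imprinted genes away from those loci, of 1 imprinted gene per cluster over the whole list and of promoter peak width in the replicated list were written before their results.

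Promoters of the facial transcription factor, signalling and jaw lists carried wide peaks. As a hypothesis, facial transcription factor promoters have wider peaks than other marked promoters. The 36 marked neural crest and facial mesenchyme transcription factors had a median widest promoter peak of 2066 bp, against 699.5 bp in marked genes drawn from the same CpG deciles (95% range of 10000 draws 547.5 to 926). The 36 include Prrx1 and Meis2, which are among the 10 genes with the widest promoter peaks. Draws were not matched on fold enrichment or on the number of TSS, over which the widest peak is taken. Marked facial signalling genes had 2728 bp (matched range 555.5 to 994), jaw patterning genes 1614 bp (524.5 to 1014) and housekeeping genes 1334 bp (487 to 1003). The median fold enrichments of these 4 lists were 10.03, 15.7, 11.8 and 13.8, each above its matched range, which reached at most 10.3. The forebrain and eye list, which includes the jaw genes Dlx1 and Dlx2, had 1810 bp (441 to 1248), with a fold enrichment of 7.40 inside its matched range (4.82 to 12.2). The epithelial list had 429 bp (418.5 to 1107) with a fold enrichment of 4.18, below its matched range of 4.63 to 10.4. Endothelium, with 5 marked genes, had 329 bp (326 to 1309), with a fold enrichment of 3.34 also below its range (3.78 to 11.1). Widths differed between lists of peaks. In the lists of replicates 1 and 2 the facial transcription factors had 1618 bp (matched range 402.5 to 739) and 1238 bp (387.5 to 684). The signalling, jaw and housekeeping lists were also above their matched width ranges in both, while forebrain and eye was above in replicate 1 (1069 bp, 324 to 931) and inside in replicate 2 (679 bp, 304 to 923). Cartilage and bone, inside its range in the replicated list (1174 bp, 379 to 1192), was above it in replicate 1 (768 bp, 237.5 to 718.5). Epithelium was below its range in replicate 2 (262 bp, 302.5 to 729), as was the intestine and pancreas list (200 bp, 220 to 1233). Endothelium was below its range in replicate 1 (232.5 bp, 241.5 to 706.5). The jaw list's fold enrichment in replicate 2 (7.94) lay inside its range (4.69 to 8.10). Width is therefore not particular to face genes, since housekeeping promoters shared it.

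Imprinted loci recurred among the domains with the most bases in peaks and the genes with the most distal peaks, such as the H19 region, Mest beside the Cpa genes, Nnat near Src, and Grb10 beside Fignl1. Of 50 imprinted genes listed from general knowledge, Ddc and Nnat had 28 distal peaks each, Blcap and Dlk1 26, Mest 24, Igf2r 18 and Igf2 15. The 50 had a median of 2.5 (random lists 0 to 1, permutation test, p = 2e-05, the smallest possible), but this list includes the loci that prompted it. The hypothesis that imprinted genes as a class have more distal peaks than other genes was tested on the 36 genes more than 300 kb from those loci, whose median was 2 (95% range of random lists 0 to 1, permutation test, p = 0.0187). Imprinted genes more often having a marked promoter may account for this. Of the 36, 24 were marked, and random lists with as many marked promoters ranged from 0 to 2 (median of the 36 genes 2, permutation test, p = 0.0952). Neighbouring imprinted genes counting the same peaks several times may too. With 1 gene per cluster the median of 19 genes away from those loci was still 2, inside the wider range of random lists of 19 genes (0 to 2, permutation test, p = 0.115). The same test on the whole list (26 genes, median 2, random lists 0 to 1.5, permutation test, p = 0.0405) decided nothing, because that list holds the loci seen first. Beyond those loci neither explanation was excluded. Whether the peaks lie on 1 parental allele was not tested.

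The replicate 1 list was 2.16 times as long as that of replicate 2. Extra peaks that miss a q of 0.05 do not account for all of it, since the ratio at a q of 0.05 or less was 1.69. Nor were all of the extra peaks scattered at random over the genome, though the test cannot tell whether a part of them was. Of 35707 distal peaks that only the replicate 1 list held and that overlapped no replicated peak, 39.8% lay within 10 kb of a replicated peak, against at most 12.8% in 100 shuffles. A test with the homeodomain consensus decided nothing, because its odds ratio lay below 1 both in 40710 distal peaks that only the replicate 1 list held, with or without a replicated peak (0.79), and in replicated distal peaks. Differences in depth, in the control files and between the embryo pools stay open and may each contribute, and none could be tested from peak lists.

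The X chromosome held fewer peaks per Mb than every autosome. Fewer genes per Mb on the X do not account for all of it, with 0.483 peaks per protein-coding gene on the X and 0.868 to 1.66 on the autosomes. Promoters poorer in CpG on the X account for much of the low marking but not all. Autosomal genes of the same CpG deciles would be marked in 30.0% of cases (95% range 27.6 to 32.3) and all autosomal genes in 43.7%, while the X had 24.5%. Lower enrichment at X promoters was seen. The median fold enrichment of marked X promoters was 5.57, against 6.39 (5.85 to 7.10) in autosomal promoters of the same CpG deciles. Mappability and the share of each sex were not tested, and no biological explanation was tested.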
